A study of Homo sapiens with 15 samples.

How the data were processed

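Total RNA was sequenced from 15 libraries in 5 groups of 3 replicates: the cell lines WPMY1, LNCaP and PC3, and PC3 after transfection with a plasmid for c-Myc-V5-6xHis or c-Myc-CfaN. Per the labels, RNA was purified with RNeasy Plus mini columns, depleted of ribosomal RNA and made into stranded libraries with NEBNext kits. Transfection used Lipofectamine with 0.75 µg of plasmid, and RNA was harvested 24 hours later. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

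The deposited files hold 2 tables of expected counts per gene, not scaled. One, made by the authors with RSEM, holds PC3 and both transfected groups. The other holds WPMY1, LNCaP and PC3. The labels name RSEM as the tool and GRCh38 as the build for all samples, but the name of the second deposited table points to salmon. Its values were not whole numbers for 14.6% to 17.0% of all listed genes, against 4.20% to 4.56% in the first, at a tolerance of 1e-06. Versions, aligner, trimming, strand setting and any length scaling are not stated. The same 3 PC3 libraries are in both tables, so cell lines and transfections were fitted separately, and no groups were compared across tables. Of 13406 genes with a mean of at least 50 counts in these PC3 libraries, 87.6% differed by under 10% between the tables and 2.10% differed over 2-fold.

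Total counts per library ran from 59013379 to 80595898. At this depth 3 counts over a group of 3 libraries correspond to about 0.0152 CPM in WPMY1 (CPM, edgeR's counts scaled to a fixed library size after TMM). Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over that group. Where it had 1 to 3 counts, any ratio given stands with its exact counting interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

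Expected counts were rounded, filtered with filterByExpr (minimum count 10), scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood fit on group. A total of 17803 genes were tested among the cell lines and 15310 among the transfections. Adjusted p-values are Benjamini-Hochberg over all genes of a comparison. A gene was called at adjusted p under 0.05, with an absolute log2 fold change of at least 1 also required between cell lines. Levels are CPM, as mean with SD, and the SE of a log2 fold change is its size divided by the root of the F statistic. This SE is too narrow where a group has few counts, so for 1 to 60 counts in a group any ratio is given with a 95% interval from the counts alone. Some such genes are given only as CPM in each group, and levels under 3 counts over a group are not firm. On simulated data with known changes, 4-fold changes were called for 97% to 100% of genes in the 6 comparisons. Changes were planted only in genes with about 1 CPM or more in WPMY1 (cell lines) or PC3 (transfections). No simulated library deviated as a whole, so these shares do not cover weaker genes or a deviating library. The share called at 2-fold was 37.3% to 52.2% between cell lines, where 2-fold is the minimum itself, and 89.6% to 97% among transfections. Of 1.5-fold changes, 56.7% to 68.7% were called among transfections.

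A total of 24 gene lists were fixed before the data were examined, and all their members but 1 matched the tables, using synonyms from the RefSeq gene table. They are Myc-induced nucleolar, Myc-induced metabolic, Myc-repressed and Myc network genes, RNA polymerase I and III, ribosomal protein, interferon, NF-kB, integrated stress response and unfolded protein response, sterol, heat shock and oxidative stress, G1/S, G2/M and p53 target genes, then androgen receptor and luminal, epithelial, stromal, basal, neuroendocrine, leukocyte and endothelial, antigen presentation, cancer-testis, splicing factor and STE20-like kinase genes. Each list was tested against all other genes with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 72 list tests of a table. It was repeated with a correlation estimated from the data and with fry. Named genes follow a rule also fixed before the data were examined. SLK, MYC and MAX are always named. The 5 called genes with the largest rise and fall are named among those with 10 CPM or more in the higher group and no overlap between the groups' libraries, a separation that chance gives 10% of genes. For a list that passes, or is described as part of the study's question or as background, up to 4 called members with the largest change are named, or 2 if none is called. Ribosomal protein genes are given only as a group.

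The alternatives were RLE size factors, DESeq2 1.42.0, no or a stricter low count filter, the replicate letter as a block, only the 6 libraries of a comparison, another fold minimum, leaving out each replicate, and the other list tests. Leaving out the small RNA genes of RNA polymerase III (RN7SL1, RN7SL2, RN7SL3, RN7SK, RPPH1, RMRP), and PC3 replicate C between the constructs, was added after the data were seen. The other splits of each 6 libraries into 3 and 3 were fitted, and 20 simulations gave the covariance of fold changes that a shared control group alone produces. Gene positions and lengths come from GENCODE v44. The study's own question on splicing of SLK needs reads per exon or transcript, which gene counts do not hold, so it was not tested. Levels of genes that mark sex were left out. The knockout and chromatin experiments that the design text mentions are not among these samples and were not analysed here.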

Results

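The data are counts of total RNA per gene in 15 libraries, 3 from each of 5 groups. WPMY1 is labelled healthy prostate and is a stromal cell line. LNCaP and PC3 are labelled metastatic prostate cancer lines, LNCaP with and PC3 without the androgen receptor (AR). PC3 was also transfected with plasmids for c-Myc-V5-6xHis, a tagged c-Myc, or c-Myc-CfaN, c-Myc joined to the N-terminal part of a split intein. No mock or empty vector transfection is among the samples. The WPMY1 libraries A, B and C held 80595898, 69273957 and 64993662 counts and the LNCaP libraries 76503810, 59939484 and 72202118. The PC3 libraries held 70441302, 76899977 and 78597975 counts in the cell line table and 68843304, 75076396 and 79112949 in the transfection table. The Myc-V5 libraries held 74263875, 59013379 and 68299730 counts, and the Myc-CfaN libraries 71350400, 67827581 and 73710474.

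One PC3 library, replicate C, stood apart from replicates A and B. RN7SL1, the RNA of the signal recognition particle, took 10.85% of its counts in the transfection table, against 5.34% and 4.60% in A and B. All small RNA genes of RNA polymerase III together took 21.8%, against 12.2% and 10.72%. In the transfected libraries that share was 14.34% to 15.89%. In the cell line table it was 18.42% in PC3 replicate C, 10.81% and 9.31% in A and B, 3.99% to 5.31% in WPMY1 and 7.03% to 9.67% in LNCaP. The median absolute log2 difference between genes was 0.304 and 0.362 from C to A and B, and 0.0974 between A and B. In the other groups it was 0.0651 to 0.109.

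The study's question concerns SLK, a STE20-like kinase, and MYC, with MAX, the DNA-binding partner of c-Myc. On GRCh38, SLK lies on chromosome 10 from 103967140 to 104029233 on the plus strand, with 19 exons. MYC lies on chromosome 8 from 127735434 to 127742951 on the plus strand, with 3 exons. MAX lies on chromosome 14 from 65006174 to 65102695 on the minus strand, with 5 exons in its canonical transcript. Values here sum all transcripts of a gene, so they hold no measure of SLK splicing.

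Among the cell lines, SLK RNA was lowest in PC3. It stood at 102 ± 2.46 CPM in WPMY1, 105 ± 0.833 in LNCaP and 44.9 ± 2.83 in PC3 (SD, n = 3). The log2 fold change of PC3 was -1.18 ± 0.07 (SE) against WPMY1 and -1.22 ± 0.07 against LNCaP, with adjusted p = 8.76e-08 and 5.09e-08. LNCaP and WPMY1 differed by 0.04 ± 0.07 in SLK, with adjusted p = 0.620, which did not pass. MYC RNA was highest in WPMY1, at 164 ± 3.58 CPM, against 84.7 ± 1.85 in LNCaP and 134 ± 0.773 in PC3. Its log2 fold change was -0.96 ± 0.06 in LNCaP and -0.30 ± 0.06 in PC3 against WPMY1, with adjusted p = 8.45e-08 and 0.000743. Both differences exceeded the replicate error but lay under the fold minimum. MAX stood at 50.5 ± 1.53 CPM in WPMY1, 35.9 ± 0.784 in LNCaP and 109 ± 7.08 in PC3.

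**Figure D1:**
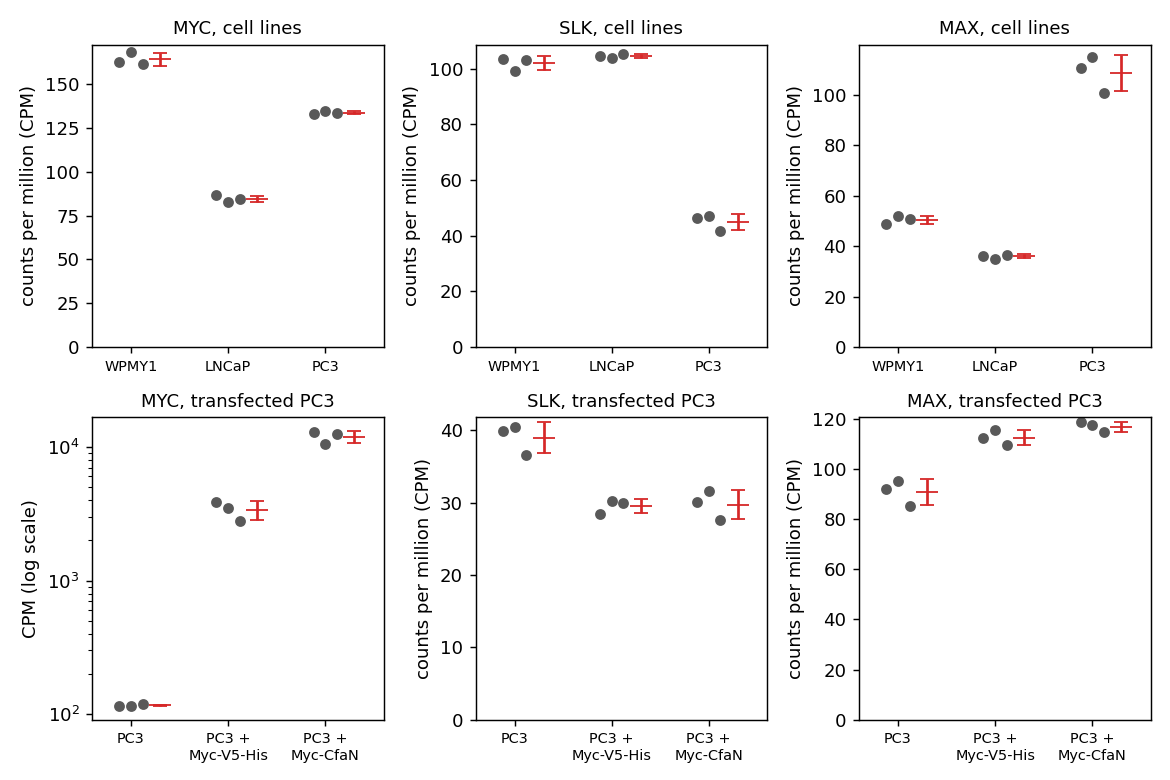
CPM values of MYC, SLK and MAX (vertical axes, logarithmic only for MYC after transfection) in each library of the cell line table (top) and the transfection table (bottom). Grey points are replicates and red bars the mean with its SD (n = 3); SLK is lowest in PC3 among the cell lines, and MYC rises to a mean of 3380.2 and 11908 with the constructs.

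The first comparison set LNCaP against WPMY1. Stromal genes were far lower in the libraries labelled LNCaP: 36 of 43 fell and 3 rose. TGFBI, an extracellular matrix protein, stood at 0.0372 against 5828 CPM, COL1A2, a chain of type I collagen, at 0.0228 against 3088, and MYL9, a smooth muscle myosin light chain, at 0.0263 against 359.5. FAP, a fibroblast protease, had no count in LNCaP and was at least 2340-fold lower. Of the heat shock and oxidative stress genes 17 of 20 fell, with NQO1 at -5.32 ± 0.09 and HSPB1 at -2.69 ± 0.18 (log2, SE). HSPA1A was lower 777-fold (95% interval 577 to 1070), but its near-identical copy HSPA1B lay at 0.37 ± 0.13 (log2), and how reads were divided between the copies is not known. The stromal list had adjusted p = 1.97e-19 and the heat shock list 1.02e-07, and adjusted p = 0.00802 and 0.013 with an estimated correlation.

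Of 57 Myc-induced nucleolar genes 25 were lower in LNCaP than in WPMY1 and 2 higher. RRP12 and UTP20, factors of ribosome assembly, had log2 fold changes of -2.28 ± 0.08 and -2.21 ± 0.14 (SE), NOP16 of -1.90 ± 0.29, and the nucleoside transporter SLC29A2 of 2.84 ± 0.14. Of 50 Myc-induced metabolic genes 14 were lower and 2 higher, with TFRC, the transferrin receptor, at -3.50 ± 0.10, the glycolytic enzyme PKM at -2.64 ± 0.06, and the cell cycle genes E2F2 at 3.27 ± 0.09 and CCND2 at 2.79 ± 0.20. The adjusted p was 1.35e-07 and 0.00138, and 0.0459 and 0.0341 with an estimated correlation. Sterol genes fell in 18 of 28 and rose in 2, with LDLR, the low density lipoprotein receptor, at -3.60 ± 0.11, MSMO1 at -2.80 ± 0.13 and TM7SF2 at 2.95 ± 0.10 (adjusted p = 1.29e-05, and 0.029 with an estimated correlation). NF-kB genes fell in 13 of 26 and rose in 1, with TNFAIP2 at -5.37 ± 0.14 and the chemokine CCL2 lower 130-fold (95% interval 83.1 to 217) (adjusted p = 0.00115, and 0.0368 with an estimated correlation).

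Epithelial genes rose in 24 of 35 and fell in 7, with the protease inhibitor SPINT2 at 76.0 against 0.104 CPM (list adjusted p = 0.00256). Neuroendocrine genes rose in 13 of 16 and fell in 2, with the adhesion molecule NCAM1 at 79.9 CPM against 3 counts in WPMY1 (ratio 5230, 95% interval 1790 to 25300) and INSM1, a neuroendocrine transcription factor, at least 448-fold higher (list adjusted p = 0.00542). All 8 measured cancer-testis genes rose, among them MAGEA3 by at least 2070-fold (list adjusted p = 0.000418). Only these 8 of 24 fixed members passed the low count filter, and 5 of them had a group without a count. A gene can pass that filter through 1 line alone, so the shared direction is partly set by it. The same limit applies to the neuroendocrine list, of which 16 of 19 fixed members passed and 2 had a group without a count. Of p53 targets 12 of 25 rose and 1 fell, with BBC3, a promoter of apoptosis, at 4.30 ± 0.15 (list adjusted p = 0.00218). Interferon genes fell in 26 of 42 and rose in 8, with PARP14 lower 1170-fold (95% interval 656 to 2350) (list adjusted p = 0.000192). Of its 11 counts in LNCaP 8 were in 1 library, a spread that this interval does not cover. Antigen presentation genes fell in 9 of 17 and rose in 2, with the immunoproteasome subunit PSMB8 at -6.29 ± 0.32 (list adjusted p = 0.00439). G2/M genes fell in 13 of 40, with ANLN at -2.64 ± 0.14 (list adjusted p = 0.000249). With an estimated correlation these lists no longer passed, in this order at adjusted p = 0.192, 0.127, 0.113, 0.191, 0.0836, 0.287 and 0.317.

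Androgen receptor and luminal genes, described because the labels give the receptor status, were called higher in 12 of 26 and lower in 3 in LNCaP against WPMY1, and the list did not pass (adjusted p = 0.372). HOXB13, a homeobox gene of the prostate lineage, was at least 1170-fold higher at 17.9 CPM. FOLH1, TMPRSS2 and KLK4 also had no count in WPMY1 but stood at only 2.11, 0.794 and 0.531 CPM in LNCaP. Rankings here and below are by fitted log2 fold change, in which a gene without a count in 1 group has no firm place. Among genes with 10 CPM or more in the higher group and no overlap between libraries, as in every such ranking below, the largest rises were those of IRS4, an insulin receptor substrate, GPC3, a glypican, HS6ST2, a heparan sulfate sulfotransferase, CACNA1H, a calcium channel, and WSCD1. They had no count in WPMY1 and were at least 48900-, 9190-, 7950-, 6880- and 5470-fold higher. The largest fitted falls under that rule were those of S100A6 and HIST1H3G, at least 29500- and 14500-fold, and of TGFBI, COL1A2 and CLDN11. SERPINE1, with 31 counts in LNCaP, was lower 37700-fold (95% interval 26600 to 55500), above the bound of HIST1H3G, whose place is therefore not firm. CLDN11 had 1 count in LNCaP, a ratio of 282000 with a 95% interval of 50600 to 11100000. In all, 8959 of 17803 genes were called, 5433 higher and 3526 lower, and 14166 without the fold minimum.

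PC3 against WPMY1 asks the same of the line without AR. All 35 epithelial genes were higher in PC3. GRHL2 and OVOL1, transcription factors of epithelial identity, were at least 6240- and 1770-fold higher, and the membrane protease ST14 stood at 420.1 against 0.0510 CPM. Of 15 basal genes 11 rose and none fell, among them the laminin chain LAMB3 by 8.92 ± 0.13 and the integrin ITGB4 by 10.19 ± 0.18 (log2, SE). Of 43 stromal genes 36 fell and 4 rose, with POSTN, a matrix protein, at least 5660-fold lower and MMP2, a matrix protease, lower 10600-fold (95% interval 7090 to 16800). NF-kB genes rose in 20 of 26 and fell in 1, with the chemokines IL8 at 6.50 ± 0.14 and CXCL6 at 7.15 ± 0.19. These lists had adjusted p = 7.74e-20, 2.27e-06, 9.45e-15 and 3.95e-07, and with an estimated correlation adjusted p = 0.0160, 0.0160, 0.00802 and 0.013.

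Interferon genes rose in 23 of 42 and fell in 7, with the antiviral enzyme OAS1 higher 220-fold (95% interval 151 to 334) (list adjusted p = 0.000418, and 0.127 with an estimated correlation). Androgen receptor and luminal genes rose in 13 of 26 and fell in 3, with HOXB13 at least 16300-fold, TMPRSS2 at least 1370-fold and C1orf116 4290-fold (95% interval 2720 to 7240) (list adjusted p = 0.00613, and 0.257 with an estimated correlation). Sterol genes fell in 12 of 28 and rose in 3, with INSIG1 at -3.06 ± 0.10 and FDFT1 at -2.83 ± 0.08 (list adjusted p = 0.000633, and 0.0735 with an estimated correlation). Ribosomal protein genes fell in 14 of 79 and rose in 4 (adjusted p = 0.00613, and 0.609 with an estimated correlation). G2/M genes fell in 8 of 40, with KIF20A at -1.80 ± 0.07 (list adjusted p = 0.000907, and 0.359 with an estimated correlation). Stress response genes fell in 9 of 32 and rose in 3, with ATF3 at 2.50 ± 0.10 and DDIT4 at -1.75 ± 0.20 (list adjusted p = 0.0451, and 0.317 with an estimated correlation). Of the Myc-induced genes 3 nucleolar and 3 metabolic members were higher and 6 and 5 lower, and neither list passed (adjusted p = 0.206 and 0.175).

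Under the same rule, the largest fitted rises in PC3 against WPMY1 were those of the protease inhibitor PI3, HOXB13, the trefoil factor TFF1, WSCD1 and GRHL2, all without a count in WPMY1. Their bounds were 29400-, 16300-, 14500-, 11300- and 6240-fold. ST14 was higher 8230-fold (counting interval 4480 to 17200) and KRT17 10400-fold (2880 to 86100). Both ratios lay above the bound of GRHL2, whose place is therefore not firm, though both intervals reach below it. STAT3, a transcription factor of cytokine signalling, the metallothionein MT1E, HIST1H4F, POSTN and HEXA, a lysosomal enzyme, had no count in PC3 and were at least 8660-, 7750-, 5750-, 5660- and 5520-fold lower. Places among the falls are not firm either. THY1 was lower 11000-fold (counting interval 5820 to 24100) and MMP2 10600-fold (7090 to 16800), both ratios above these bounds. In all, 7180 genes were called, 4192 higher and 2988 lower, and 12735 without the fold minimum.

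PC3 against LNCaP compares the cancer lines directly. Epithelial genes were higher in PC3 in 31 of 35 and lower in none, with a median log2 fold change of 6.14, also with members at 0 set to their bound. The keratin KRT19 stood at 1327 against 0.00727 CPM and TACSTD2, a surface glycoprotein, was at least 14100-fold higher. Interferon genes rose in 33 of 42 and fell in 2, with PARP14 higher 1400-fold (95% interval 783 to 2810, though 8 of its 11 LNCaP counts were in 1 library). NF-kB genes rose in 23 of 26, with IL8 higher 2300-fold (95% interval 1660 to 3290). Heat shock genes rose in 15 of 20 and fell in 1, with HSPA1A higher 2450-fold (95% interval 1820 to 3380) but its near-identical copy HSPA1B at 0.33 ± 0.13 (log2, SE), and basal genes rose in 11 of 15 and fell in 3, with LAMC2 at 8.53 ± 0.09. These lists had adjusted p = 2.52e-14, 2.67e-09, 9.12e-10, 6.86e-06 and 0.000481, and with an estimated correlation adjusted p = 0.0169, 0.029, 0.00802, 0.0160 and 0.035.

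Of the Myc-induced nucleolar genes 25 of 57 were higher in PC3 than in LNCaP and 1 lower, among them the mitochondrial transcription factor TFB2M at 2.39 ± 0.16 and RRP9 at 2.16 ± 0.15. Of the metabolic ones 13 of 50 were higher and 4 lower, with TFRC at 3.48 ± 0.10, LDHA, lactate dehydrogenase, at 2.55 ± 0.09, and CCND2 lower 2100-fold (95% interval 1460 to 3170). Myc-repressed genes were higher in 11 of 26 and lower in 5, with the matrix protein THBS1 at 12.19 ± 0.14 and CCND1 at 6.26 ± 0.14. The adjusted p was 4.51e-05, 0.0331 and 0.0292, and with an estimated correlation adjusted p = 0.0990, 0.127 and 0.120, so none of the 3 calls held. With the stricter low count filter the metabolic list did not pass either (adjusted p = 0.0703).

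Lower in PC3 than in LNCaP were stress response genes in 13 of 32 (3 higher), with SESN2 at -4.13 ± 0.12 and ASNS, asparagine synthetase, at -3.36 ± 0.13. So were p53 targets in 12 of 25 (5 higher), with BBC3 at -5.08 ± 0.16, neuroendocrine genes in 13 of 16 (2 higher), with NCAM1 at least 5180-fold, and all 8 cancer-testis genes that passed the filter (of 24 fixed), with MAGEA12 at least 350-fold. Of the 16 neuroendocrine genes 6 had a group without a count, so the filter can partly set the direction of that list as well. Higher were luminal genes in 13 of 26 (5 lower), with SPDEF higher 1480-fold (95% interval 986 to 2330) though AR itself, with 4 counts in PC3, was lower 1830-fold (95% interval 716 to 6730), and antigen presentation genes in 9 of 17 (2 lower), with PSMB8 at 6.17 ± 0.32. These lists had adjusted p = 0.0331, 0.0150, 0.00296, 0.00102, 0.0102 and 0.0204. With an estimated correlation none held, at adjusted p = 0.317, 0.317, 0.0571, 0.0836, 0.257 and 0.359. Adjusted over the list alone, the number of called members was the same for every list in the 3 comparisons of cell lines.

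The largest single rises in PC3 against LNCaP under that rule were those of the keratins KRT7, KRT81 and KRT19, of S100A6 and of PKP1, a desmosome protein. S100A6 was at least 93400-fold higher, and KRT81 stood at 9215 against 0.0591 CPM. KRT7 had 1 count in LNCaP and KRT19 and PKP1 had 2, with ratios of 1200000 (95% interval 216000 to 47600000), 173000 (48000 to 1430000) and 152000 (42100 to 1260000). NCAM1, MAF, FOXF2 and HEXA had no count in PC3, the last 3 at least 4450-, 4090- and 4020-fold lower, and IRS4 had 1 count (ratio 145000, interval 26100 to 5740000). CELF2 also had 1 count in PC3, with a ratio of 10800 (interval 1940 to 427000). This ratio lay above those bounds, so the places of genes at 0 are not firm. In all, 9115 genes were called, 4091 higher and 5024 lower, and 14342 without the fold minimum. Against WPMY1, both cancer lines shared 2481 genes called higher and 1256 called lower, where independent calls would share 1279 and 592, and 1064 genes were called in opposite directions.

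**Figure D2:**
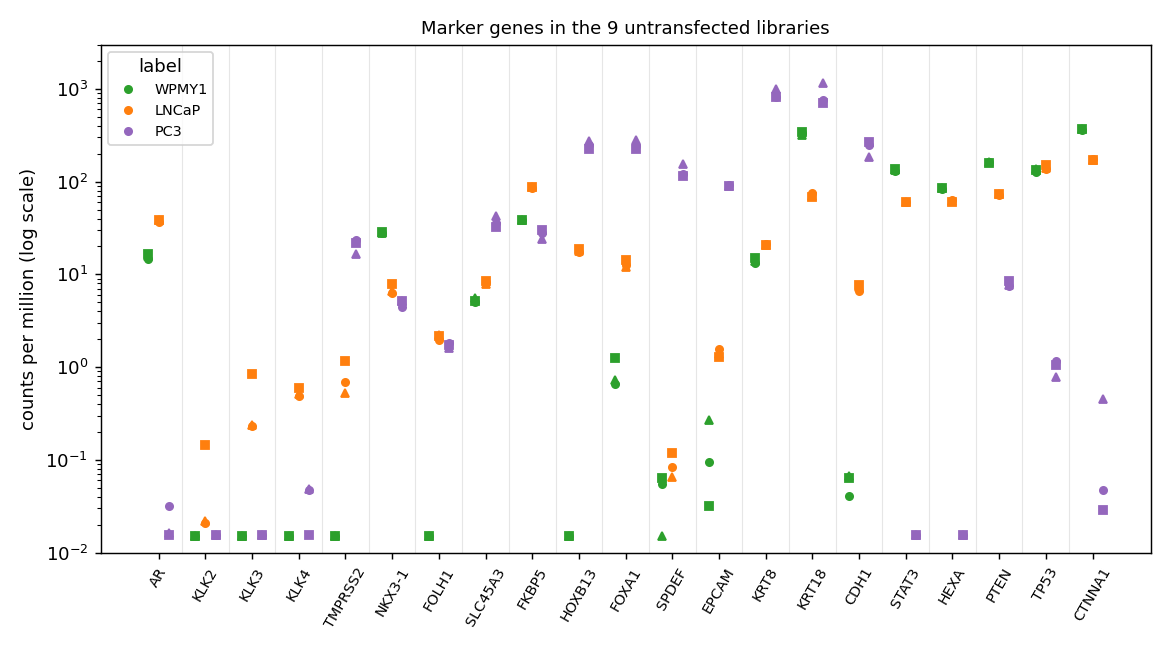
CPM values (logarithmic axis) of prostate luminal and epithelial markers and of STAT3, HEXA, PTEN, TP53 and CTNNA1 in the 9 libraries of the cell line table, chosen after their values were seen. Colours are the labels and marker shapes the replicates; values under 3 counts over the group are drawn at that floor, and KLK3 stays between 0.231 and 0.838 in the libraries labelled LNCaP.

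The transfections address whether transcription of c-Myc targets rises with both constructs. The control is untransfected PC3, so any effect of c-Myc on its targets cannot be told apart from one of transfection. These counts hold no measure of c-Myc protein or of the share of cells transfected. A list that does not pass is therefore no evidence that c-Myc leaves its targets unchanged. With c-Myc-V5-6xHis, MYC RNA rose from 117 ± 1.49 to 3380.2 ± 528 CPM (SD, n = 3), a log2 fold change of 4.86 ± 0.13 (SE, adjusted p = 2.22e-08). This count sums RNA of the cell's own gene and of the plasmid. Neither Myc-induced list passed its test: 12 of 57 nucleolar genes rose and 12 fell, and 13 of 50 metabolic genes rose and 9 fell (25 and 23 members changed adjusted over the list alone). Their adjusted p was 0.979 and 0.910, with median log2 fold changes of -0.02 and 0.04. TCOF1, a factor of ribosomal RNA transcription, had a log2 fold change of -1.15 ± 0.08, while the DNA repair enzyme UNG rose by 0.66 ± 0.06 and POLR1B, a subunit of RNA polymerase I, by 0.59 ± 0.09. NCL, nucleolin, had a log2 fold change of -0.50 ± 0.06, and TFRC of -0.50 ± 0.08. Myc-repressed genes fell in 10 of 25 and rose in 5 (15 adjusted over the list alone), with the cell cycle inhibitor CDKN1A at -1.36 ± 0.14 and CLU at -0.98 ± 0.11. That list had adjusted p = 0.0460, and adjusted p = 0.227 with an estimated correlation.

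All 48 measured interferon genes rose with the V5 construct, also adjusted over the list alone, with a median log2 fold change of 3.31, also with members at 0 set to their bound. RSAD2, an antiviral enzyme, rose from 2.76 ± 0.539 to 208 ± 23.8 CPM, by 6.24 ± 0.16 on the log2 scale. MX1 and MX2, antiviral GTPases, rose by 4.92 ± 0.15 and 5.94 ± 0.11, OASL by 5.29 ± 0.10 and IFIT1 by 5.04 ± 0.07. These 5 were the largest rises among genes with 10 CPM or more in the higher group and no overlap between libraries. The interferon genes IFNL2 and IFNL3 had no count in PC3 and rose at least 20.8- and 15.6-fold, to 0.289 and 0.213 CPM. The list had adjusted p = 3.69e-304, and adjusted p = 0.000571 with an estimated correlation. Antigen presentation genes rose in 9 of 17 and fell in 2 (11 adjusted over the list alone), with NLRC5, their transcriptional activator, at 2.67 ± 0.08, and TAP1, the peptide transporter, at 1.79 ± 0.08. Heat shock and oxidative stress genes rose in 11 of 20 (12 adjusted over the list alone), with HMOX1, heme oxygenase, at 1.13 ± 0.09 and HSPA1A at 0.71 ± 0.12. How reads were divided between HSPA1A and its near-identical copy HSPA1B is not known. The last 2 lists had adjusted p = 6.83e-06 and 0.00316, and both adjusted p = 0.190 with an estimated correlation.

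SLK fell with the V5 construct, from 39.0 ± 2.12 to 29.6 ± 1.00 CPM, a log2 fold change of -0.40 ± 0.07 (adjusted p = 0.00289) that was -0.31 with a trend over transcript length taken out, and MAX rose by 0.31 ± 0.06 (adjusted p = 0.00376). NF-kB genes fell in 16 of 27 and rose in 4, with RELB at -1.37 ± 0.17 and CXCL2 at -1.49 ± 0.17, and basal genes fell in 9 of 14 and rose in 2, with the laminin chain LAMC2 at -1.06 ± 0.05. Both counts were the same adjusted over the list alone. These lists had adjusted p = 0.000414 and 0.000268, and each passed only narrowly with an estimated correlation (adjusted p = 0.0457). Epithelial genes fell in 18 of 35 (21 adjusted over the list alone), with KRT7 at -1.41 ± 0.18 and the junction protein CGN at -1.32 ± 0.06, and stromal genes fell in 17 of 36 and rose in 7 (26 adjusted over the list alone), with COL3A1 at -2.67 ± 0.37 and COL5A1 at -1.50 ± 0.19. Their adjusted p was 0.000109 and 0.0352, and with an estimated correlation adjusted p = 0.124 and 0.139. Among genes with 10 CPM or more in PC3 and no overlap, the largest falls were those of MSMP at -3.20 ± 0.17, ACHE, acetylcholinesterase, at -3.12 ± 0.22, PMEPA1, induced by androgen and by TGF-beta, at -2.97 ± 0.09, and the mucin MUC6 at -2.48 ± 0.14. The read-through gene HNRNPUL2-BSCL2 also fell, at -2.71 ± 0.33, but its mean count in the same PC3 libraries was 3421 in one table and 7575 in the other, so its level is uncertain.

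In all, 5128 of 15310 genes changed with the V5 construct, 2364 higher and 2764 lower, and 714 of them at least 2-fold. Without PC3 replicate C the count was 7956 (3726 higher, 4230 lower), without V5 replicate A 3290, and with only the 6 libraries of the comparison 3401.

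With c-Myc-CfaN, MYC RNA reached 11908 ± 1198 CPM, a log2 fold change of 6.67 ± 0.15 (SE, adjusted p = 3.67e-09). The Myc-induced lists did not pass: 6 of 57 nucleolar genes rose and 13 fell (19 adjusted over the list alone, adjusted p = 0.629), and 10 of 50 metabolic genes rose and 10 fell (24 adjusted over the list alone, adjusted p = 0.562). The median of the metabolic list was 0.02 and its mean -0.04, so they differed in sign. The falls included TCOF1 at -0.98 ± 0.08, TFRC at -0.65 ± 0.08 and ODC1, ornithine decarboxylase, at -0.60 ± 0.05, and SORD rose by 0.67 ± 0.06. Myc-repressed genes fell in 8 of 25 and rose in 6 (15 adjusted over the list alone), with CDKN1A at -0.95 ± 0.13 and CDKN2B at 0.87 ± 0.12, and the list did not pass (adjusted p = 0.562).

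All 48 interferon genes rose with CfaN as well, also adjusted over the list alone, with a median of 3.69 (adjusted p under the smallest number the software holds, and adjusted p = 0.000571 with an estimated correlation). RSAD2 rose by 6.91 ± 0.16, MX2 by 6.41 ± 0.11, OASL by 5.89 ± 0.10 and the transcription factor BATF2 by 5.73 ± 0.14, which with MYC were the largest rises among genes with 10 CPM or more in the higher group and no overlap. IFNL2 and IFNL3 rose at least 59.2- and 52.4-fold. IFNB1, interferon beta, had 1 count in PC3 and a ratio of 250 (95% interval 44.5 to 9930). Antigen presentation genes rose in 10 of 17 and fell in 1 (11 adjusted over the list alone), with NLRC5 at 3.14 ± 0.08. Stress response genes rose in 16 of 32 (17 adjusted over the list alone), with DDIT3 at 1.11 ± 0.15 and ATF3 at 1.01 ± 0.08. Heat shock genes rose in 10 of 20 (11 higher and 1 lower adjusted over the list alone), with HSPA1A at 1.62 ± 0.12. The division of reads between HSPA1A and HSPA1B is not known here either. These 3 lists had adjusted p = 3.92e-10, 0.000255 and 0.000101, and with an estimated correlation adjusted p = 0.124, 0.163 and 0.124.

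SLK fell with CfaN to 29.7 ± 2.02 CPM, a log2 fold change of -0.39 ± 0.07 (adjusted p = 0.00340) that was -0.28 with the trend over transcript length taken out, and MAX rose by 0.36 ± 0.06 (adjusted p = 0.00161). NF-kB genes fell in 10 of 27 and rose in 5 (16 adjusted over the list alone), and the list did not pass (adjusted p = 0.406, median -0.21). G1/S genes fell in 15 of 43 (17 lower and 1 higher adjusted over the list alone), with CHAF1A at -0.66 ± 0.09. Epithelial genes fell in 16 of 35 and rose in 2 (19), stromal genes fell in 14 of 36 and rose in 5 (22), and basal genes fell in 8 of 14 and rose in 1 (11 adjusted over the list alone, as the counts before). Among these were KRT7 at -1.25 ± 0.18, the matrix protein SPARC at -3.14 ± 0.37 and LAMC2 at -0.97 ± 0.05. The adjusted p of these 4 lists was 0.0276, 0.0102, 0.0490 and 0.0105, and with an estimated correlation adjusted p = 0.227, 0.227, 0.156 and 0.124. MSMP at -3.37 ± 0.17, PMEPA1 at -2.90 ± 0.09, ACHE at -2.81 ± 0.21, MUC6 at -2.33 ± 0.14 and the cartilage collagen COL2A1 at -2.17 ± 0.34 had the largest falls among genes with 10 CPM or more in the higher group and no overlap. In all, 4685 genes changed, 2164 higher and 2521 lower, and 716 at least 2-fold. Without PC3 replicate C the count was 7873 (3534 higher, 4339 lower), and with only the 6 libraries of the comparison 3075.

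Both constructs changed 4000 genes in the same direction, 1781 higher and 2219 lower, where independent calls would share 334 and 455. Across 12655 genes, which are not independent replicates, the fold changes of the constructs correlated at r = 0.939, and the shared PC3 libraries alone gave r = 0.489 in simulations. Without PC3 replicate C 6542 genes were shared (2877 higher, 3665 lower).

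**Figure D3:**
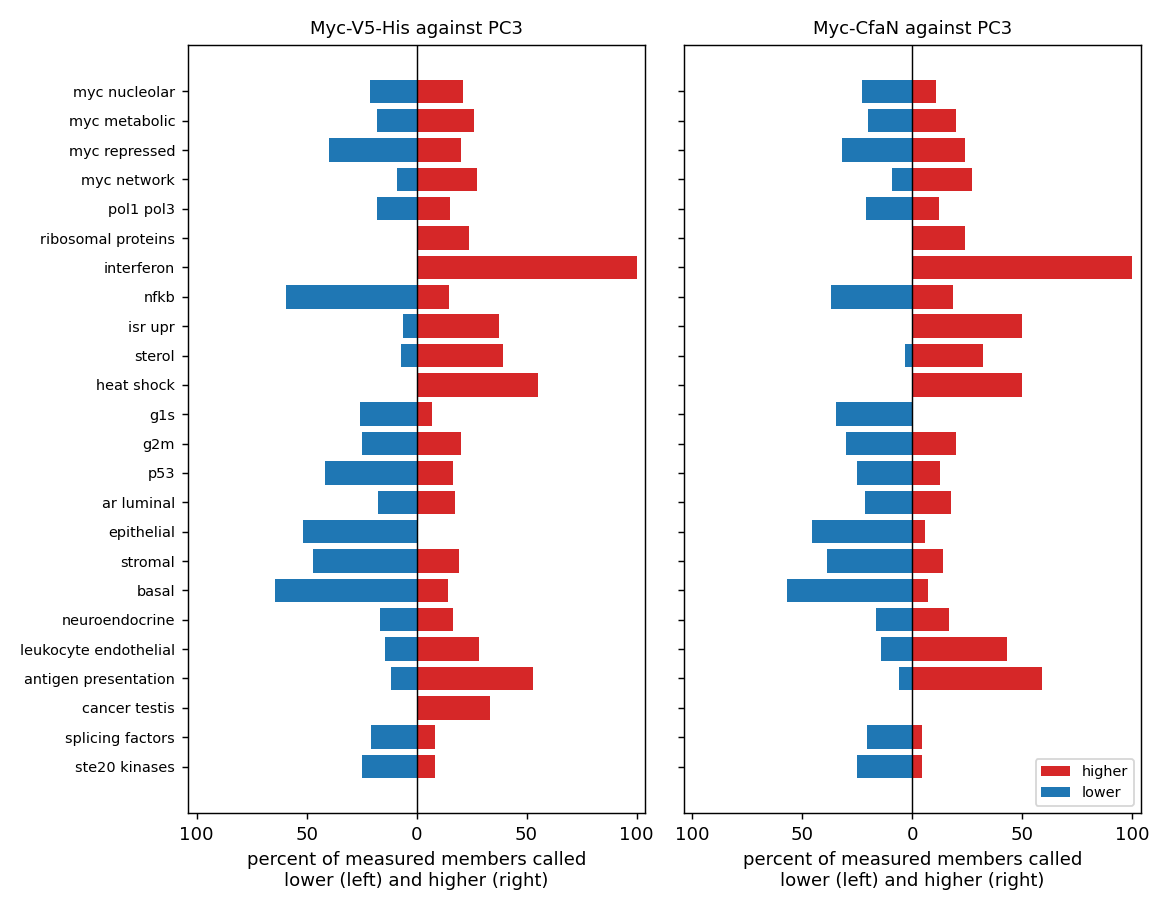
Percent of the measured members of each gene list called higher (red, right) or lower (blue, left) with c-Myc-V5-6xHis and c-Myc-CfaN against PC3, at adjusted p under 0.05. All 48 interferon genes are higher with both constructs, and the nucleolar Myc-induced list has 12 higher and 12 lower with V5 and 6 and 13 with CfaN.

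Between the constructs, MYC RNA was higher with CfaN by 1.82 ± 0.12 on the log2 scale (adjusted p = 0.000446). The heat shock genes HSPA6 and HSPA1A were higher as well, by 1.73 ± 0.22 and 0.91 ± 0.12, as were the cytokine IL6 by 0.97 ± 0.10 and the stress response factor ATF3 by 0.87 ± 0.08. For HSPA1A the division of reads with HSPA1B is not known. SLK differed by 0.01 ± 0.07 and MAX by 0.06 ± 0.06, and neither passed. Interferon genes were higher in 3 of 48 (33 adjusted over the list alone), with IFIT2 at 0.74 ± 0.07, OASL at 0.60 ± 0.08 and IFIT3 at 0.54 ± 0.07. NF-kB genes were higher in 2 of 27 (8 adjusted over the list alone), with CXCL3 at 0.49 ± 0.06, and stress response genes in 1 of 32 (10 adjusted over the list alone). No Myc-repressed gene passed over all genes and 3 of 25 did adjusted over the list alone, with the stress-induced GADD45B at 0.61 ± 0.10 and median 0.14. These 4 lists were higher with CfaN at adjusted p = 7.93e-63, 6.70e-19, 6.01e-12 and 1.65e-06. With an estimated correlation the adjusted p was much larger, at 0.0105, 0.00115, 0.0457 and 0.0457, so the last 2 passed only narrowly. Heat shock (1 of 20 called, 5 adjusted over the list alone), antigen presentation (0 of 17, and 4), basal (0 of 14, and 1) and epithelial genes (0 of 35, and 0) were higher as lists, and G1/S (0 of 43) and G2/M genes (0 of 40) lower. Their adjusted p was 0.00103, 1.34e-09, 0.00200, 0.000140, 0.000429 and 0.0474, and with an estimated correlation adjusted p = 0.153, 0.124, 0.0807, 0.125, 0.124 and 0.582.

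Myc-induced metabolic genes were lower with CfaN as a list (adjusted p = 0.00285, median -0.03, and adjusted p = 0.263 with an estimated correlation), with no member called over all genes or over the list alone. Without CfaN replicate B that list did not pass (adjusted p = 0.0618). The nucleolar list did not pass (adjusted p = 0.0671), but did so, lower with CfaN, without PC3 replicate C (adjusted p = 0.0172), CfaN replicate A (0.0250) or C (0.0217), or V5 replicate C (0.0401). In all, 17 genes were higher with CfaN and none lower in edgeR with all 9 libraries, and 934 had an unadjusted p under 0.05. That no gene was lower depends on the setting. DESeq2 called 142 higher and 15 lower. The count was 1269 (651 higher, 618 lower) without PC3 replicate C, which enters this comparison only through the shared spread, and 1525 (850 higher, 675 lower) with only the 6 libraries of the comparison. Leaving out any 1 transfected library gave 5 to 7.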

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

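The tests of luminal genes in the libraries labelled LNCaP, the one of abundant genes for the interferon list and the one of transfection without regard to MYC for SLK were chosen after the results were seen; the others were fixed before.

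The response to the constructs differed in 17 genes, all higher with CfaN, although 618 of 1269 were lower without PC3 replicate C and 675 of 1525 with only the 6 libraries. MYC RNA itself differed by 1.82 on the log2 scale. Tested directly between the constructs, the interferon, NF-kB, stress response and Myc-repressed lists were higher with CfaN, at adjusted p = 7.93e-63, 6.70e-19, 6.01e-12 and 1.65e-06, and the medians were 0.37, 0.26, 0.16 and 0.14. Their adjusted p with an estimated correlation was 0.0105, 0.00115, 0.0457 and 0.0457. Against WPMY1, more interferon genes fell than rose in LNCaP (26 and 8 of 42) and more rose than fell in PC3 (23 and 7), but with an estimated correlation neither passed (adjusted p = 0.0836 and 0.127). NF-kB genes fell in 13 of 26 and rose in 1 in LNCaP, and rose in 20 and fell in 1 in PC3 (adjusted p = 0.0368 and 0.013 with an estimated correlation). PC3 against LNCaP gave adjusted p = 2.67e-09 and 9.12e-10 for the interferon and NF-kB lists, and 0.029 and 0.00802 with an estimated correlation. SLK also differed between PC3 and LNCaP, with a log2 fold change of -1.22, as did MAX with 1.60 and MYC with 0.66.

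Luminal genes were low in the libraries labelled LNCaP, although AR itself stood at 37.6 ± 1.22 CPM (SD, n = 3), against 15.7 ± 1.05 in WPMY1 and 0.0207 ± 0.00944 in PC3. KLK3, which encodes prostate-specific antigen and is a classic androgen target, stood at 0.231 to 0.838 CPM there, KLK2 at a mean of 0.0623 and EPCAM at 1.41, against 90.8 in PC3, while NKX3-1 stood at 6.93 (28.1 in WPMY1, 4.94 in PC3), but FKBP5, also an androgen target, was highest there at 87.5 (38.5 and 27.4). A swap with WPMY1 or PC3 would place KLK3 in their libraries, if true LNCaP libraries hold KLK3, but the highest level in these 6 was 0.0144 CPM. The transfected libraries were not checked for it. Of the other measured luminal genes 4 of 25 (16%) were higher than in PC3 and 13 lower, but these genes are the pattern itself, so a mislabelled or otherwise different culture cannot be told apart from the label being right. Epithelial genes were low there too: 31 of 35 were higher in PC3 and 0 lower. KRT8 stood at 20.9 CPM against 879 in PC3, and CDH1 at 7.24 against 235. KRT18 was lowest there, at 71.1 against 332 in WPMY1 and 877 in PC3. Against WPMY1 24 of 35 epithelial genes were higher and 7 lower. WPMY1 is a stromal line with EPCAM at only 0.131 CPM and CDH1 at 0.0569, so this count does not speak for the label. No LNCaP culture of known identity was compared, so the identity of these libraries stays undecided. An androgen-poor medium was not tested directly, as androgen was not measured. The records give ordinary serum (10% FBS), and 0 of them name stripped serum or added androgen. Such a medium would bear on androgen targets, but the separate epithelial list was low too, with 31 of 35 higher in PC3 and 0 lower. FKBP5, an androgen target, was highest in LNCaP. These values argue against such a medium as the whole cause, for the epithelial genes they cover. The low KLK3 and KLK2 alone would not exclude it. A line that changed in culture was not tested, and every result on LNCaP rests on these libraries being what the label says.

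Interferon genes rose together after both transfections. A few genes that take many counts would shift all other genes by one factor, but with library sizes as the only scaling the median of the list with V5 lay 3.32 above that of the other genes (log2, where single members had a median SE of 0.15), so this is not the whole cause. A scaling moves list and other genes alike, so this difference restates the list median of 3.31 and is no independent test. Transfected plasmid DNA could raise these genes without regard to MYC, and with 0 mock or empty vector libraries in the series this and an effect of MYC cannot be told apart. The greater rise with CfaN, which had more MYC RNA, does not separate them, since the amount of plasmid taken up was not measured.

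SLK RNA was lower after both transfections. Fold changes fell slightly with transcript length over the 93.5% of genes that have one (rho = -0.0728 across genes with V5 and -0.130 with CfaN), and between PC3 replicates as well (rho = -0.362 for C against A and B, and -0.289 for A against B). With the length trend taken out SLK still lay at -0.31 ± 0.07 with V5 and -0.28 ± 0.07 with CfaN (log2, SE), and without PC3 replicate C at -0.45 ± 0.05 with each, so neither length bias nor that library alone is the whole cause. They were not taken out together. Replicate C itself varied with length, so the larger fall without it is not corrected for length and is no stronger evidence. Transfection without regard to MYC stays open, with 0 mock libraries, and an effect of MYC on SLK is an untested hypothesis that an empty vector would address.

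For each comparison all 10 splits of its 6 libraries into 3 and 3 were fitted on those libraries alone, which are too few for a share under 0.05. The real split called 8754 genes for LNCaP against WPMY1, 6554 for PC3 against WPMY1 and 8914 for PC3 against LNCaP, and 3401 for V5 and 3075 for CfaN against PC3, and the highest other split called 0 in each. Between the constructs it called 1525 and the highest other split 4. In each comparison 1 of the 10 splits, the real one, gave as many. The PC3 libraries shared by both transfection comparisons, and the WPMY1 libraries shared by the cell lines, can create overlap. In 20 simulations the constructs shared 0 calls and the cell lines a mean of 0.05, but these leave out all effects and do not show how many the shared libraries add among genes that change. The covariance of fold changes was 0.212 for the constructs against 0.0118 simulated, and 1.63 against 0.0201 for the cell lines. The correlation across genes, which are not independent, was 0.939 against 0.489 simulated for the constructs, but 0.376 against 0.533 for the cell lines, and a difference of correlations does not measure a shared effect. The 3 control libraries cannot be split between the comparisons, so the part of the excess that they cause was not removed.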

How the results depend on the processing

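Only the settings without small RNA genes, and without PC3 replicate C between the constructs, were chosen after the data were seen. Counts for the cell lines moved over 1.5 times only without the fold minimum, to 14166 (LNCaP against WPMY1), 12735 (PC3 against WPMY1) and 14342 (PC3 against LNCaP). Among the transfections a 2-fold minimum gave 714 (V5), 716 (CfaN) and 5 (CfaN against V5), since fewer genes can pass, and only the 6 libraries of the comparison gave 3401, 3075 and 1525. Between the constructs DESeq2 gave 157 and the replicate block 7, where the same letter across groups did not pair libraries (r from -0.0692 to 0.0922). Leaving out single replicates gave 3290 to 7956 (V5), 3157 to 7873 (CfaN), 5 to 1269 (CfaN against V5) and 2846 to 6542 genes shared by the constructs. Each highest count was without PC3 replicate C, 3290 without V5 replicate A and 5 without V5 replicate B, and the cause of the others was not tested.

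MYC, and SLK among the cell lines, kept direction and call in every setting run. List values are adjusted p. For PC3 against LNCaP the metabolic list gave 0.0703 with the stricter filter and 0.127 with an estimated correlation, and the nucleolar list 0.0990 with the latter. For PC3 against WPMY1 fry, which asks only whether a list moves, gave 0.000470 (nucleolar) and 7.85e-06 (metabolic). Between the constructs the nucleolar list gave 0.0302 without a filter, 0.0246 with only 6 libraries and 0.0172 to 0.463 without single replicates, and the metabolic list 0.263 with an estimated correlation, 0.0866 with fry and 0.000492 to 0.0618 without single replicates. The nucleolar list with V5, never past the threshold, changed direction with the stricter filter (0.977), with only 6 libraries (0.956) and without V5 replicate C or PC3 replicate C (0.710 to 0.953 over single replicates). SLK between the constructs, never past it either, changed sign without single replicates (-0.048 to 0.058). The cause of these changes was not tested.

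Of 279 other gene results 19, and of 59 other list results 38, changed in some setting. One fit of all 15 libraries was not run, because the tables were made separately. Depth limits genes near 3 counts per group, given as bounds.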

Other observations

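Splicing regulators as a list passed in no comparison, but single members differed widely between the cell lines. ESRP1 and ESRP2, regulators of epithelial splicing, stood at 122 ± 24.9 and 65.9 ± 1.36 CPM in PC3 (SD, n = 3), against 0.296 and 0.424 in LNCaP and 0.0206 and 0.278 in WPMY1. NOVA2 and CELF2, regulators best known from neurons and from muscle and brain, stood at 19.3 ± 2.38 and 55.5 ± 0.985 CPM in LNCaP, against 0.333 and 0.00538 in PC3 and 0.00906 and 0.133 in WPMY1. CELF2 had only 1 count in PC3 and NOVA2 only 2 in WPMY1, so these 2 levels are not firm. All LNCaP levels here rest on the label, since luminal markers were low in the same libraries. Of 50 members 7 were higher and 9 lower in LNCaP than in WPMY1 (adjusted p = 0.456, median -0.32 but mean 0.45), and 7 and 7 in PC3 (adjusted p = 0.248). Over all genes 50.3% and 40.3% were called in these comparisons. With the constructs 4 of 48 rose and 10 fell with V5, and 2 and 10 with CfaN, among them HNRNPM at -0.79 ± 0.24 and -0.76 ± 0.24 (log2, SE), while HNRNPC rose by 0.55 ± 0.08 and 0.52 ± 0.08. These counts were the same adjusted over the list alone, and the list had adjusted p = 0.986 and 0.629. Of 24 STE20-like and Hippo kinases, SLK among them, 6 fell with each construct and 2 rose with V5 and 1 with CfaN, with MINK1 at -0.63 ± 0.06 and -0.53 ± 0.06 (the same counts adjusted over the list alone, list adjusted p = 0.199 and 0.242). In the cell lines TNIK and PAK1 were lower in PC3 than in WPMY1, at -2.41 ± 0.16 and -2.24 ± 0.09.

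Among cell cycle genes MKI67, CENPE and CENPF fell most with both constructs, while the G2/M list did not pass (adjusted p = 0.423 with V5 and 0.157 with CfaN). MKI67, the proliferation marker Ki-67, changed by -2.18 ± 0.21 with V5 and -1.83 ± 0.21 with CfaN, the centromere protein CENPE by -2.20 ± 0.18 and -2.01 ± 0.17, and CENPF by -1.71 ± 0.11 and -1.57 ± 0.11. With V5 10 of 40 G2/M members fell and 8 rose (20 adjusted over the list alone), and with CfaN 12 fell and 8 rose (22). With V5 the median was 0.01 and the mean -0.14. Of sterol genes 11 of 28 rose and 2 fell with V5 and 9 rose and 1 fell with CfaN (15 and 10 adjusted over the list alone), with LDLR at 0.83 ± 0.06 and 0.88 ± 0.06 (list adjusted p = 0.0508 and 0.157). Ribosomal protein genes rose in 19 of 79 with each construct and fell in none (18 adjusted over the list alone), and the list did not pass (adjusted p = 0.195 and 0.231). RNA polymerase I and III genes rose in 5 of 33 and fell in 6 with V5, and rose in 4 and fell in 7 with CfaN (12 and 11 adjusted over the list alone), with UBTF, an activator of ribosomal RNA transcription, at -0.78 ± 0.09 and -0.78 ± 0.09 (list adjusted p = 0.861 and 0.475). Of 11 Myc network members 3 rose and 1 fell with each construct (4 adjusted over the list alone), with MXI1 at 0.74 ± 0.13 and 0.64 ± 0.13 (list adjusted p = 0.799 and 0.600). In the cell lines MYCL stood at 15.7 ± 0.748 CPM in LNCaP, 4.25 ± 0.279 in PC3 and 0.364 ± 0.0445 in WPMY1.

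Of 19 markers of leukocytes and endothelium, cell types that a pure culture should lack, 10 were left by the low count filter. As a list these did not pass in the cell lines (adjusted p = 0.677, 0.677 and 0.282). That test compares the lines with each other, so it does not show how pure a culture was. CD68, also known from other cells, stood at 42.0 CPM in WPMY1, 1.17 in LNCaP and 36.4 in PC3, and CD19 at 1.12 in LNCaP without a count in the other lines. In the PC3 libraries, genes chosen after their values were seen were absent or low: STAT3 and HEXA had no count, CTNNA1 stood at 0.176 ± 0.239 CPM against 367 in WPMY1, TP53 at 1.00 ± 0.188 against 133, and PTEN at 7.91 ± 0.54 against 160. AR was nearly absent from PC3, as its label says.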
